A study of Mus musculus with 11 samples.

How the data were processed

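RNA sequencing was done on dissected corpus callosum, the large tract of myelinated axons that joins the hemispheres, and on primary neurospheres, free-floating clusters of neural stem and progenitor cells grown from the subventricular zone (SVZ), the germinal layer that lines the lateral ventricles. Tissue came from wild-type mice and from mice labelled Bmal1-/-, aged 8 to 10 weeks. Per the labels' protocols, SVZ cells were dissociated mechanically and cultured for 1 week in expansion medium with 20 ng/ml EGF and 2 ug/ml heparin. RNA was enriched for mRNA or depleted of rRNA, the labels not saying which for any library, then fragmented, reverse transcribed with random primers and sequenced on the BGISEQ-500 platform. Reads were aligned with STAR 2.7.1a to the mouse genome build mm10, per the submitters' processing notes. The gene annotation used for counting is not given in the sources used here.

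The files deposited by the authors hold raw read counts per gene for 24411 gene symbols, preceded by 4 rows of reads not assigned to a gene. Counts that ignored strand (the 2nd column) were used. Counts on either strand were close to equal (49.6% to 50.8% on the first), so the libraries were taken as unstranded, and reads from overlapping genes on opposite strands could not be told apart. Of 80 genes examined by name, 18 have an exon overlapped by a gene on the opposite strand. The 4 unassigned rows were left out of library sizes and tests. Unmapped reads took 7.77% to 8.46% of reads in callosum libraries and 13.7% to 22.6% in neurosphere libraries. Reads outside annotated genes took 8.55% to 9.93% and 14.5% to 16.6%, and ambiguous reads 1.17% to 1.40% and 0.772% to 0.977%. These shares did not overlap between the sources, so a difference in library preparation cannot be told apart from source. Reads mapping to several places were listed at 0, so genes with near-identical copies are undercounted or split. To mark such genes, the share of each named gene's 50-base stretches that also occurs in transcripts of another gene of GENCODE M21 was computed. Gene positions are from the RefSeq annotation of GRCm38.p6, the same assembly as mm10, and 99.6% of the symbols had one. Transcript length and GC content came from the longest GENCODE M21 transcript, matched for 95.8% of the symbols.

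Samples were grouped by the labels into 4 groups: wild-type neurospheres (n = 3), neurospheres labelled Bmal1-/- (n = 3), wild-type callosum (n = 3) and callosum labelled Bmal1-/- (n = 2). The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. The sum of gene counts was 17450270 to 19717848 per library, the largest 1.13 times the smallest. A gene with no count in a library may still lie at up to 3 counts of that library's total. Such floors cover counting error only. Replicate pairs were compared with a chi-square statistic over genes, which was 7.17 to 140 per degree of freedom within groups, far above sampling noise, so every library was kept as a replicate of its own.

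The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust = TRUE and glmQLFTest, two-sided), with TMM scaling, genes kept by filterByExpr, and Benjamini-Hochberg adjustment. A gene is called here when its adjusted p is under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Each RNA source was fitted on its own for the genotype comparison, the wild-type groups were compared across sources, and the genotype by source interaction was tested in 1 model of all 11 libraries. Levels are given as CPM, counts scaled to library size and by TMM within the libraries of a comparison, as mean ± SD. For 31 gene lists covering the clock, cell types of the brain, proliferation and metabolic and stress pathways, camera of limma 3.58.1 was run on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, for lists with at least 3 tested members. Beside it, camera with an estimated correlation and fry were run. The estimated correlation passed no list in any comparison. This included G2 and M phase between wild-type sources, where 25 of 25 genes were lower (camera adjusted p = 0.766). Failing that setting therefore does not show that a list was unchanged. The estimated correlation was far above the preset 0.01 for many lists, such as 0.952 for striatal neurons in the callosum and 0.855 for S phase in neurospheres. It lay below the preset for others, such as 0.000159 for the E-box targets in the callosum. For lists with a high correlation, p-values of camera with the preset value are too small. Overlap of calls was tested with Fisher's exact test, two-sided.

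The comparisons, gene lists, main tests and the rule for naming genes were set before the data were examined. Named genes were Arntl and the clock list in every comparison, the 8 largest rises and 8 largest falls among called genes of at least 2 CPM with no overlap between groups (5 each between sources; unnamed gene models left out), up to 4 called members per list by smallest p, and the called genes of the interaction. Where fewer than 5 genes passed in a direction, the 5 smallest p-values in that direction were named and said not to pass, except 1 gene that is not reported here. Alternatives set beforehand were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter at 5 CPM, the replicate number as a block, 1 model of all libraries, a threshold of 2-fold and leaving out each library. Added after seeing the data were offsets for transcript length and GC content (splines with 5 degrees of freedom per library), the same without 1 neurosphere library, and the level of striatal genes as a covariate in the callosum.

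The procedure was tested on simulated counts with the means, depths and dispersions of these libraries and 200 changed genes. For neurospheres, over 13968 genes, edgeR recovered 35 of 100 genes changed 2-fold and 89 of 100 changed 4-fold. For the callosum, over 14198 genes, it recovered 76 and 100 of 100, and 10.2% of its calls were false. For the interaction, over 15322 genes, it recovered 4 and 81 of 100. Between wild-type sources, over 14733 genes, it recovered 79 and 97 of 100, and 14.6% of its calls were false. The 200 changed genes all had a mean of at least 2 CPM. The real data called 12645 genes between wild-type sources and 1 in neurospheres. As the number of changed genes moves the adjusted threshold and the scaling, these shares may not carry over to the real comparisons.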

Results

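The data comprised 11 RNA-seq libraries from mice, 6 from SVZ neurospheres (3 wild type, 3 labelled Bmal1-/-) and 5 from dissected corpus callosum (3 wild type, 2 labelled Bmal1-/-). Bmal1, listed under the gene symbol Arntl, encodes the transcription factor that pairs with CLOCK to drive the circadian clock. The design sets genotype against genotype within each RNA source, in a study of the clock in callosum and SVZ during demyelination. Gene counts summed to 17450270 to 19717848 per neurosphere library and 17513165 to 17836955 per callosum library, and between 16716 and 17076 genes had a count in a library.

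The targeted gene was examined first. Arntl (chromosome 7, 113178471 to 113314126, mm10) stood at 52.1 ± 6.48 CPM (SD, n = 3) in wild-type neurospheres and 51.7 ± 4.78 CPM (SD, n = 3) in those labelled Bmal1-/-, a log2 fold change of -0.01 ± 0.17 (SE, edgeR adjusted p = 0.983). In the callosum it stood at 29.5 ± 2.7 CPM (SD, n = 3) and 30.1 ± 4.59 CPM (SD, n = 2), a log2 fold change of 0.03 ± 0.14 (SE, edgeR adjusted p = 0.943). The count of Arntl therefore did not fall in either set of libraries labelled Bmal1-/-. The labels do not say which part of the gene was removed, a count over the whole gene does not show the loss of a few exons, and a gene on the opposite strand overlaps Arntl. Arntl itself thus gives no check of the genotype labels, and every direction below is that of the libraries labelled Bmal1-/-.

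In the callosum, some clock genes were lower in the libraries labelled Bmal1-/- and others higher. Dbp, a transcription factor of the clock output, fell from 96.0 ± 8.87 CPM (SD, n = 3) to 13.1 ± 0.706 CPM (SD, n = 2), a log2 fold change of -2.87 ± 0.13 (SE, edgeR adjusted p = 4.9e-05). Per3, a period gene, fell by 2.23 ± 0.12 (SE) on the log2 scale, Nr1d2, which encodes the repressor REV-ERB beta, by 2.80 ± 0.25, and Ciart, a repressor of the clock, by 2.47 ± 0.22. Nr1d1, which encodes REV-ERB alpha, fell by 0.93 ± 0.14. Npas2, which encodes a partner of BMAL1 related to CLOCK, rose by 0.98 ± 0.11, the repressor Cry1 by 1.20 ± 0.16, and Nfil3, a repressor of the genes that DBP activates, by 1.35 ± 0.16. Of the 14 E-box targets of CLOCK and BMAL1, 6 fell (10 when adjusted over the list alone) and 0 rose. The sixth was Usp2, at -0.57 ± 0.10, named here after its value was seen, whose call ended when any 1 of the 5 libraries was left out. Of the 6 tested targets of ROR and REV-ERB, 3 rose (3 when adjusted over the list alone), and of the 25 core clock genes 3 rose and 5 fell (3 and 9 when adjusted over the list alone). Per1, at a log2 fold change of -0.01 ± 0.15, and Per2, at 0.21 ± 0.13, did not pass, nor did Tef at -0.57 ± 0.12 (edgeR adjusted p = 0.0766). Levels of clock genes vary over the day, and no time of collection entered any comparison. A clock gene that did not pass here may therefore differ at another time. With fry the E-box targets passed as lower (adjusted p = 0.014), whereas the ROR and REV-ERB targets (0.0733) and the core clock (0.0539) did not pass. With a preset correlation, camera placed the E-box targets lower (adjusted p = 5.01e-11), the ROR and REV-ERB targets higher (adjusted p = 9.62e-05) and the core clock lower (adjusted p = 0.031). With an estimated correlation none of these held (adjusted p = 0.147, 0.541 and 0.626), and the core clock did not pass without wild-type replicate 1 (0.063) or replicate 1 labelled Bmal1-/- (0.0918). Without wild-type replicate 3 the calls of Nr1d1 (edgeR adjusted p = 0.16), Npas2 (0.0709) and Cry1 (0.118) ended, and that of Nr1d1 also ended without either replicate labelled Bmal1-/- (0.169 and 0.0636). In the single model of 11 libraries Nr1d1 (0.435), Ciart (0.0609), Npas2 (0.0632) and Nfil3 (0.448) did not pass, with the same signs, and reads of Dbp and Nr1d1 could not be told apart from those of genes overlapping them on the opposite strand.

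**Figure D1:**
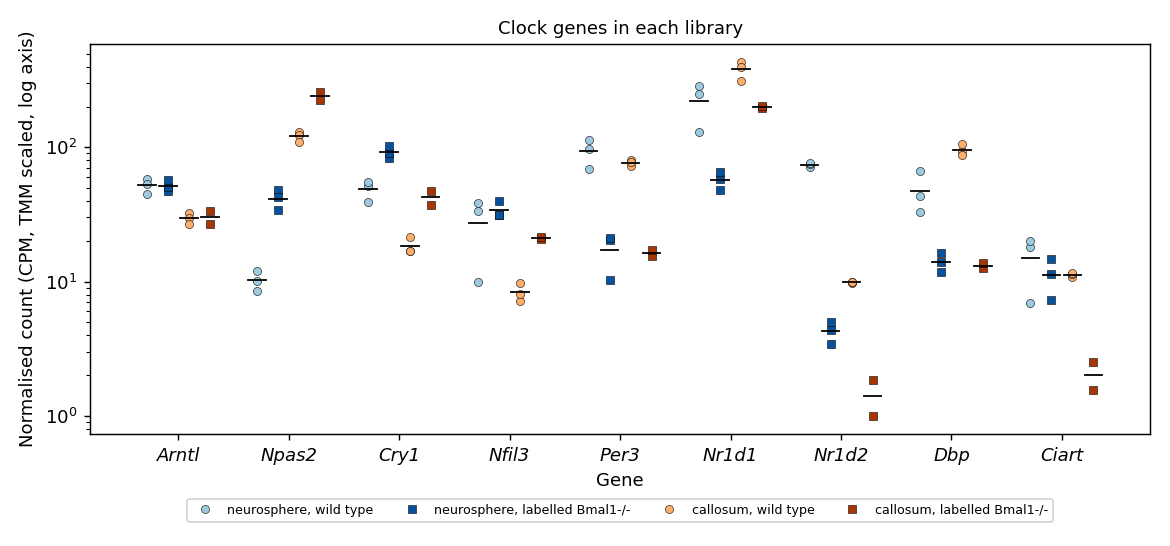
Normalised counts of 9 clock genes in each library, on a log axis in CPM after TMM scaling within each RNA source. Each point is a library and each bar the mean of its group. Arntl did not separate the genotype labels, whereas Nr1d2 stood at 71.2 to 75.9 CPM in wild-type neurospheres and 3.43 to 4.99 CPM in those labelled Bmal1-/-.

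Some genes that astrocytes raise in reactive states, 4 of the 28 tested, were called higher in the callosum libraries labelled Bmal1-/-. Gfap, the intermediate filament of astrocytes, rose 4.56-fold, from 293 to 403 CPM in the wild-type libraries to 1552 and 1619 CPM (log2 fold change 2.19 ± 0.14, SE, edgeR adjusted p = 0.000194). The complement gene C4b rose by 3.49 ± 0.18 on the log2 scale, the protease inhibitor gene Serpina3n by 1.60 ± 0.12 and Aspg, which encodes an asparaginase, by 1.60 ± 0.24. No gene of the list fell (7 higher and 1 lower when adjusted over the list alone), and 18 of the 28 had a log2 fold change above 0. The list as a whole was placed higher by camera (adjusted p = 0.00135), which did not hold with an estimated correlation (adjusted p = 0.626). General astrocyte markers did not follow. Of 17 tested, Gfap rose, Aldh1l1, an enzyme of folate metabolism, fell by 0.55 ± 0.10 (edgeR adjusted p = 0.0491), and the median log2 fold change was 0.01 (4 higher and 1 lower when adjusted over the list alone). The call of Aldh1l1 ended in 10 of 14 alternatives, among them RLE scaling (adjusted p = 0.0533), and that of Aspg ended without wild-type replicate 2 (0.0583), wild-type replicate 3 (0.118) or the replicate labelled Bmal1-/- 1 (0.156). In the single model of 11 libraries Gfap (adjusted p = 0.226), Serpina3n (0.139) and Aspg (0.139) did not pass, with log2 fold changes of 2.17, 1.59 and 1.58, and C4b was the 1 of the 4 that did. C4a shares 35.2% of the 50-base stretches of C4b, so part of the C4b count is uncertain.

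Among neural stem and progenitor genes in the callosum, Fabp7, a fatty acid carrier of radial glia, rose by 3.27 ± 0.37 and the transcription factor gene Sox3 by 3.02 ± 0.15 on the log2 scale, and the other 18 of 20 tested did not pass (2 higher and 1 lower when adjusted over the list alone). The largest rises by the naming rule were those of Spon2 (4.69 ± 0.52), C4b, Egfl6 (3.49 ± 0.34), the chemokine gene Cxcl5 (3.46 ± 0.43), Fabp7, A2m, an inhibitor of proteases (3.17 ± 0.47), Sox3 and Hebp2 (2.80 ± 0.32). The largest falls were those of Etnppl, a phospholyase of astrocytes (-5.88 ± 0.41), Slc25a34 (-4.15 ± 0.31), Chil1, which encodes a chitinase-like protein (-3.66 ± 0.27), Gkn3 (-3.35 ± 0.44), Kirrel2 (-3.21 ± 0.20), Dbp, Nr1d2 and Nphs1, which encodes nephrin (-2.79 ± 0.36). Kirrel2 (30447766 to 30457515) and Nphs1 (30458207 to 30488623) lie side by side on chromosome 7, as does Arntl further along, so their falls may not be separate. The wild-type mean of Spon2, 0.150 CPM, lay below the floor of 3 counts per library (0.168 to 0.171 CPM), so the size of its rise is uncertain. Etnppl stood at 6.67 to 10.7 CPM in wild type and at 0.117 and 0.172 CPM in the libraries labelled Bmal1-/-, close to the floor (0.170 and 0.169 CPM). In the single model of 11 libraries Cxcl5 (edgeR adjusted p = 0.0564), Gkn3 (0.0645) and Nphs1 (0.0564) did not pass, nor did A2m (0.12) and Cxcl5 (0.0712) with the striatal covariate. Without wild-type replicate 3 the calls of Spon2 (adjusted p = 0.0525), Cxcl5 (0.0622), Fabp7 (0.0626), A2m (0.0585), Hebp2 (0.0585) and Nphs1 (0.0525) ended, with the same sign. Without replicate 1 labelled Bmal1-/- the calls of Cxcl5 (0.0519), Fabp7 (0.0511), A2m (0.119), Gkn3 (0.0608) and Nphs1 (0.0939) ended, and that of A2m also ended without replicate 2 labelled Bmal1-/- (0.0539) or wild-type replicate 2 (0.0712).

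**Figure D2:**
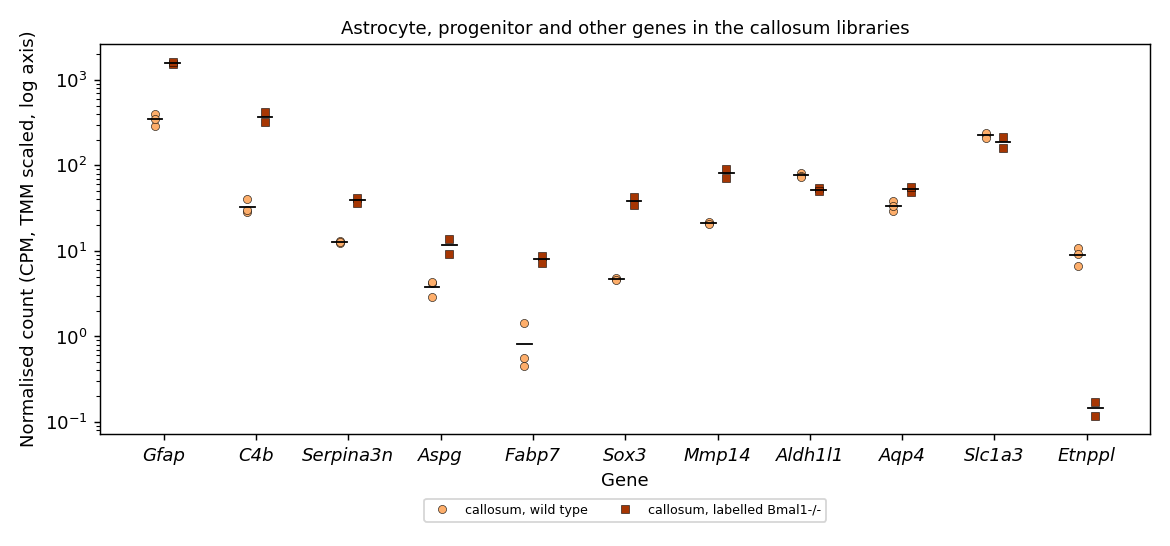
Normalised counts of 11 genes in the 5 callosum libraries, on a log axis in CPM after TMM scaling. Each point is a library and each bar the mean of its group. Gfap, C4b, Serpina3n and Sox3 lay higher in both libraries labelled Bmal1-/- than in any wild-type library, Etnppl lay lower, and the astrocyte genes Aqp4 (log2 fold change 0.65 ± 0.14) and Slc1a3 (-0.29 ± 0.14) did not pass.

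No called gene lay in the lists of mature oligodendrocyte and myelin genes (25 tested, median log2 fold change 9.71e-05), oligodendrocyte precursors (20, 0.05), microglia (19, 0.14), disease-associated microglia (17, 0.28), mature neurons (19, 0.03) or neuroblasts (16, -0.03). When adjusted over the list alone, 4 genes of disease-associated microglia were higher and 1 of mature neurons was lower. Camera placed the disease-associated microglia list higher (adjusted p = 0.000394, and 0.541 with an estimated correlation). The median level of mature neuron genes was 626 to 797 CPM over the callosum libraries, and that of myelin genes 116 to 195 CPM. The dissected tissue therefore held neuronal RNA, and the changes in it cannot be placed in white matter alone. Marker lists of neighbouring tissue held no called member. The 12 striatal neuron genes had a median log2 fold change of -1.28, and their median level was 79.1, 264 and 140 CPM in the wild-type libraries against 44.8 and 83.0 CPM in those labelled Bmal1-/-. The 7 tested choroid plexus genes had a median of -1.20, the 13 ependymal genes -0.52, and the 14 genes of pericytes, smooth muscle and fibroblasts -0.39 (2 choroid plexus genes and 1 pericyte gene were lower when adjusted over the list alone). The striatal (adjusted p = 1.47e-05), choroid plexus (0.0187) and pericyte (0.0251) lists passed camera as lower, and none held with an estimated correlation (0.844, 0.916 and 0.916). The pericyte list did not pass without wild-type replicate 1 (0.0532), wild-type replicate 2 (0.104) or replicate 1 labelled Bmal1-/- (0.724). The ependymal list did not pass (0.0703). Endothelial genes (15 tested) and the 3 sex-linked genes tested held no call, with medians of 0.00 and -0.33, and 1 blood gene was tested, at -0.37.

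Of the pathway lists in the callosum, the glucocorticoid response held 1 call, Cdkn1a, an inhibitor of the cell cycle (1.07 ± 0.17), and glycolysis and hypoxia held 1, the glycolytic gene Pgk1 (1.06 ± 0.18), 68.0% of whose 50-base stretches occur in other transcripts. When adjusted over the list alone, 1 of 13 glucocorticoid genes was higher and 4 lower, and 1 of 21 glycolysis genes was higher. Both calls ended when single libraries were left out, among them wild-type replicate 3 (adjusted p = 0.186 and 0.215). The lists of S phase, G2 and M phase, cholesterol synthesis, antioxidant, interferon, immediate early, stress response, respiratory chain, ribosomal protein and guidance genes held no call. When adjusted over the list alone, 1 antioxidant gene was higher and 2 lower, and 1 interferon and 1 immediate early gene were higher. The respiratory chain list was placed higher by camera (median 0.30, adjusted p = 0.031, and 0.916 with an estimated correlation). Its median level was higher in 1 library alone, replicate 1 labelled Bmal1-/- (105 CPM, against 68.2 CPM in replicate 2 and 70.0 to 71.9 CPM in wild type), without which the direction turned (0.316), and it did not pass without wild-type replicate 1 (0.0911).

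Over the 14198 genes tested in the callosum, 74 rose and 55 fell at an adjusted p under 0.05 by edgeR, 76 of the 129 by at least 2-fold. The count was 330 with DESeq2 and 33 in the single model of 11 libraries, and it was 27 without wild-type replicate 3, 73 without wild-type replicate 2 and 49 without replicate 1 labelled Bmal1-/-. Of the 129 genes, 17 were called in every one of 15 settings, among them C4b, Dbp, Nr1d2, Per3, Sox3, Etnppl and Mmp14, and no gene changed sign in a setting that tested it.

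In neurospheres, 1 of 13968 genes passed. Nr1d2 (chromosome 14, 18204056 to 18239106) fell from 74.1 ± 2.61 CPM (SD, n = 3) to 4.27 ± 0.726 CPM (SD, n = 3), a log2 fold change of -4.11 ± 0.20 (SE, edgeR adjusted p = 0.000403), and was called in every one of 16 settings. No gene rose at an adjusted p under 0.05 by edgeR. At an unadjusted p under 0.05 there were 422 genes, 3.02% of those tested. DESeq2 called 34, of which 20 were higher, limma-voom called 2, and the single model of 11 libraries called 19. Among the smallest p-values of higher genes, none of which passed, were those of Npas2 (2.02 ± 0.21, edgeR adjusted p = 0.091), the mitochondrial carrier gene Ucp2 (2.22 ± 0.28), Arhgef3 (2.02 ± 0.25) and the Notch ligand gene Dll4 (2.07 ± 0.27). After Nr1d2, the smallest among lower genes, also not passing, belonged to Trim30d (-3.56 ± 0.43), Per3 (-2.43 ± 0.31, edgeR adjusted p = 0.11), Trim12a and Inpp4b (-2.04 ± 0.27). Per3 did pass with the replicate number as a block (edgeR adjusted p = 0.0246), with offsets (0.0291) and with no filter (0.0474). It did not pass when any library was left out. The mean of Trim30d in the libraries labelled Bmal1-/-, 0.156 CPM, lay at the floor of 3 counts per library (0.152 to 0.172 CPM), so the size of its fall is uncertain. Trim12a had 70 counts over the wild-type libraries and 0 over those labelled Bmal1-/-, at least 23-fold lower against a floor of 3 counts over the group.

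Dbp, Nr1d1 and Cry1 had values of the same sign in neurospheres as in the callosum but did not pass. Dbp stood at -1.76 ± 0.28 (edgeR adjusted p = 0.218), Nr1d1 at -1.95 ± 0.30 (0.218) and Cry1 at 0.93 ± 0.18 (0.532). In the single model of 11 libraries Dbp (adjusted p = 0.00934), Nr1d1 (0.00934), Per3 (0.00222) and Npas2 (0.000627) passed in neurospheres, and Cry1 (0.114) did not. Of the 14 E-box targets, 1 fell (4 when adjusted over the list alone). Of the 25 core clock genes, 1 fell (2 higher and 4 lower when adjusted over the list alone), and of the 6 tested ROR and REV-ERB targets none passed (2 higher when adjusted over the list alone). Camera placed the E-box targets lower (adjusted p = 1.87e-09), the core clock lower (0.00515) and the ROR and REV-ERB targets higher (0.0222), which did not hold with an estimated correlation (adjusted p = 0.661, 0.771 and 0.661). The core clock did not pass without replicate 1 labelled Bmal1-/- (0.0871), and the ROR and REV-ERB targets did not without wild-type replicate 1 (0.213) or replicates 2 or 3 labelled Bmal1-/- (0.123 and 0.0544). The ROR and REV-ERB targets also did not pass with the replicate number as a block (camera adjusted p = 0.0608).

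No member of any other list was called in neurospheres by edgeR. Camera placed higher the lists of ribosomal proteins (median log2 fold change 0.45, adjusted p = 9.48e-07), the respiratory chain (0.43, 9.48e-07), G2 and M phase (0.12, 0.00864), cholesterol synthesis (0.16, 0.00864) and S phase (0.16, 0.0236). None held with an estimated correlation (adjusted p = 0.771, 0.771, 0.771, 0.661 and 0.771). When adjusted over the list alone, 1 neural stem gene and 2 pericyte genes were higher. The replicate 1 labelled Bmal1-/- stood apart from the other neurosphere libraries, with 22.6% of reads unmapped against 13.7% to 16.2%, and its deviation from the others fell with transcript length (Spearman rho = -0.672 across 13487 genes, which are not independent replicates). Without that library the medians of the ribosomal protein, respiratory chain and S phase lists were 0.09, 0.10 and -0.02, and 5 genes were called, 3 higher and 2 lower: Npas2, Arhgef3, Ucp2, Nr1d2 and Inpp4b. Camera still placed the ribosomal protein and respiratory chain lists higher without that library, at an adjusted p under 0.05. The S phase list did not pass camera without it (adjusted p = 0.34), wild-type replicate 2 (0.334) or replicate 2 labelled Bmal1-/- (0.115), and turned lower without wild-type replicate 3 (0.991). G2 and M phase did not pass without wild-type replicate 3 (0.211) or replicates 2 or 3 labelled Bmal1-/- (0.093 and 0.352), nor did cholesterol synthesis without wild-type replicate 1 (0.0968) or the same 2 replicates labelled Bmal1-/- (0.115 and 0.0781). The microglia list had a median of 0.65 over all libraries and -0.34 without replicate 1 labelled Bmal1-/-. The lists of oligodendrocytes, precursors, stem cells, neuroblasts, astrocytes, reactive astrocytes, disease-associated microglia, neurons, striatal neurons, endothelium, pericytes, ependyma, antioxidant, interferon, immediate early, glucocorticoid, stress response, glycolysis and guidance genes did not pass camera.

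**Figure D3:**
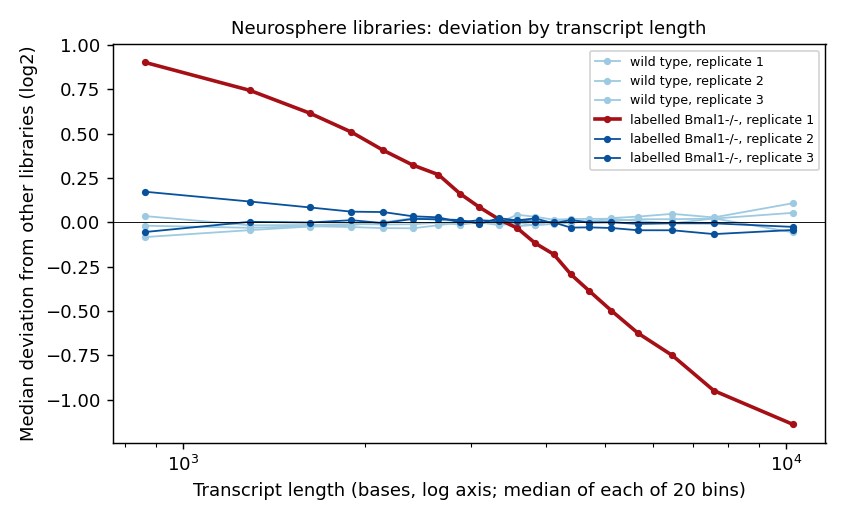
Median log2 deviation of each neurosphere library from the mean of other neurosphere libraries, in 20 bins of transcript length on a log axis in bases. Replicate 1 labelled Bmal1-/- was set against 5 libraries, and each of the others against 4, with that replicate left out. Replicate 1 labelled Bmal1-/- lay above the others for short transcripts and below for long ones, with medians of 0.63 in the shortest of 4 equal groups of genes and -0.77 in the longest.

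The genotype difference was tested between the sources in 15322 genes, and it differed in 2 by edgeR, with 656 at an unadjusted p under 0.05 and 37 called by DESeq2. By Xist and Kdm5d, given below, every neurosphere library was female and every callosum library male. A genotype difference that depends on sex could therefore not be separated from a dependence on source. Library preparation may also have differed between the sources and was not separated. C4b rose in the callosum and stood at a log2 fold change of -0.20 ± 0.23 in neurospheres, a difference of -3.67 ± 0.33 (SE, edgeR adjusted p = 0.00165). Mmp14, which encodes a membrane-bound matrix metalloproteinase, rose by 1.94 ± 0.13 in the callosum and stood at 0.03 ± 0.17 in neurospheres, a difference of -1.89 ± 0.22 (SE, edgeR adjusted p = 0.0115). The call of Mmp14 ended without wild-type neurosphere replicate 2 (adjusted p = 0.0533), any wild-type callosum replicate (0.0533, 0.0735 and 0.1) or callosum replicate 2 labelled Bmal1-/- (0.149), whereas C4b was called in all 20 settings. Without replicate 1 labelled Bmal1-/- of the neurospheres the count was 10. The smallest p-values that did not pass belonged, toward neurospheres, to Kirrel2 (3.94 ± 0.61), Gstt1 (2.53 ± 0.40), Dll4 (2.19 ± 0.36), Ucp2 (1.82 ± 0.34) and Cdc42ep3 (1.45 ± 0.28), and toward the callosum to A2m (-3.32 ± 0.49), Col18a1 (-1.39 ± 0.22) and Slc20a2 (-1.27 ± 0.22). Kirrel2 stood at 0.104 and 0.176 CPM in wild-type neurospheres and those labelled Bmal1-/-, near the floor, so its genotype difference there is uncertain. No clock gene passed, and C4b was the called member of the reactive astrocyte list. Camera placed the striatal neuron, ependymal and choroid plexus lists higher (adjusted p = 0.0178 each), and none held with an estimated correlation (0.97 each).

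Among 12953 genes tested in both sources, 1 called gene was shared, Nr1d2 (0.00332 by chance, two-sided Fisher's exact p = 0.00332 for lower genes). At an unadjusted p under 0.01 in both, 15 higher genes (0.948 by chance, Fisher's exact p = 6.56e-15) and 10 lower genes (0.653 by chance, Fisher's exact p = 4.41e-10) were shared. They included Npas2, Cry1, Sox3, Fabp7, Spon2 and Ucp2 among higher and Nr1d2, Per3, Dbp, Nr1d1 and Chil1 among lower genes. Of the 110 genes called in the callosum and tested in both, 92 had the same sign in neurospheres, against 61.7% of all genes. Fold changes depended on GC content and transcript length in the same directions in both sources. Spearman rho was 0.267 and -0.582 across genes in neurospheres, and 0.313 and -0.186 in the callosum. Part of the 61.7% may therefore be technical, which was not tested.

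Between wild-type sources, the striatal neuron genes were higher in the callosum in 12 of 12 (median log2 fold change 8.37). Mbp, the myelin basic protein gene, was higher in the callosum by 5.19 ± 0.21 on the log2 scale, Mag by 4.12 ± 0.16 and Fa2h, which makes myelin lipids, by 4.53 ± 0.16, and 22 of 25 myelin genes were higher and 1 lower. The median of the myelin genes was 2.60. Neuronal genes were higher in 18 of 19 (median 7.54), among them Rbfox3 (8.89 ± 0.18) and Slc17a7, a glutamate transporter (11.03 ± 0.24), microglial genes in 18 of 19, among them Tmem119 (8.20 ± 0.28), and endothelial genes in 13 of 15. All 25 genes of G2 and M phase were lower in the callosum, among them Cenpe (-6.57 ± 0.17) and Hmmr (-7.28 ± 0.23), as were 22 of 25 of S phase. Of 20 stem and progenitor genes 13 were lower, among them Egfr, the receptor of the EGF in the medium (-6.41 ± 0.19), and Fabp7 (-9.23 ± 0.32), and 5 higher. Among core clock genes 9 were higher, such as Npas2 (4.13 ± 0.15), and 11 lower, such as Rorb (-5.07 ± 0.13) and Nr1d2 (-2.35 ± 0.11), and Arntl did not pass (-0.26 ± 0.13). Time of day was not accounted for in these clock gene differences. Of 21 glycolysis and hypoxia genes 18 were lower and 1 higher, and of 22 antioxidant genes 17 were lower, such as Hmox1 (-5.12 ± 0.14), and 3 higher. By the rule of largest size, Cck, a neuropeptide gene, had 20462 counts over the wild-type callosum libraries and 1 over the wild-type neurosphere libraries. In all, 6195 genes were higher and 6450 lower of 14733 tested. The fold change rose with GC content (Spearman rho = 0.57 across 14210 genes, which are not independent replicates), and with offsets for length and GC content 2480 of the 12645 calls (19.6%) changed sign. Without TMM scaling the median of all genes moved from -0.06 to -0.57, with 4979 calls higher and 7696 lower (39.3% higher against 49.0%). Xist, transcribed from the inactive X of females, stood at 709 to 3093 CPM in every neurosphere library and at most 0.219 CPM in the callosum, and the Y-linked Kdm5d at 4.37 to 7.71 CPM in the callosum and 0 counts in neurospheres, so sex and source could not be separated. Library preparation could not be separated from source either.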

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

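The tests on genes near Arntl and the fit with striatal genes as a covariate were chosen only after the results were seen. The other tests were set down beforehand.

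The genotype difference of C4b differed between the sources by -3.67 on the log2 scale and that of Mmp14 by -1.89, each neurospheres minus callosum in the interaction test. Both stand here because the interaction test passed. Sex could not be separated from source in that test. The share of unmapped reads, which enters no comparison, reached 22.6% in the neurosphere library labelled Bmal1-/- replicate 1.

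Gfap, C4b and Serpina3n were higher in the callosum libraries labelled Bmal1-/-. A larger share of astrocytes is argued against, since the 16 astrocyte genes other than Gfap had a median log2 fold change of -0.0231 (95% bootstrap interval -0.14 to 0.31), and depth is too, since the largest callosum library held 1.02 times the counts of the smallest. The bootstrap resampled the 16 genes, so its interval does not cover the spread between libraries. A difference in dissection stays open, because the striatal neuron genes had a median of -1.28 but 0 of 12 were called, and their level in a wild-type library (79.1 CPM) lay below that in a library labelled Bmal1-/- (83.0 CPM). With that level as a covariate the 3 genes kept their calls, at log2 fold changes of 2.48 ± 0.12, 3.91 ± 0.13 and 1.58 ± 0.17 (SE, edgeR), which speaks against less striatal tissue as their whole cause, whereas Aspg, the fourth called gene of the reactive list, lost its call (1.65 ± 0.38, adjusted p = 0.128). The 7 tested choroid plexus genes also had a median log2 fold change of -1.20, with 0 called. The median level of 3 of them was 0.699 and 0.975 CPM in the libraries labelled Bmal1-/-, against 1.92 to 3.71 CPM in wild type. That level was not fitted as a covariate, so choroid plexus, or a region not covered by the lists, may contribute. A change in the state of astrocytes with the genotype label stays open, as a hypothesis that was not tested further.

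The neurosphere library labelled Bmal1-/- replicate 1 stood apart. Lower depth is argued against, since with all libraries thinned to the same total its highest correlation with another was 0.937, below the lowest of the other pairs (0.97). A bias with transcript length, as degraded RNA can give, may account for it, with a Spearman rho of -0.672 across genes. Among the other libraries, replicate 3 labelled Bmal1-/- lay at -0.233 and replicate 2 at 0.00495, and the wild-type libraries at 0.027 to 0.102. A weaker bias of the same sign was thus present in replicate 3, so transcript length was not fully separated from the genotype label in neurospheres. The values of the other libraries had replicate 1 labelled Bmal1-/- left out of their reference. Microglia are also an open source, since their 16 tested genes, also expressed in neurospheres, deviated by a median of 2.07 on the log2 scale in this library, the largest of 5 lists of other cells. C1qa stood at 61.1 CPM there, against 5.89 to 18.5 CPM in the other neurosphere libraries.

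Genes near Arntl were among the smallest p-values. Within 20 Mb of Arntl, the odds of an unadjusted p under 0.01 were higher in neurospheres (odds ratio 5.76, 95% interval 2.50 to 11.7, Fisher's exact p = 6.52e-05) but not clearly in the callosum (1.54, 0.941 to 2.39, p = 0.0593), so a chromosome segment of the donor strain, which would be carried in both sources, cannot be told apart from other causes. Without Trim genes, whose copies can share reads, the neurosphere odds ratio was 3.25 (1.02 to 8.05), so shared reads cannot be excluded as part of it. The share of 50-base stretches that also occur in other genes was low for the Trim genes named here, 4.59% for Trim12a and 8.29% for Trim30d. It was not computed for other Trim genes. Genes with an unadjusted p under 0.01 and the same sign in both sources, a set examined after these results, had an odds ratio of 8.19 (2.03 to 24.5, Fisher's exact p = 0.00236), and of 6.22 (1.18 to 21, p = 0.0164) without Trim genes. The 4 genes within the window were Ucp2, Coa4, Stard10 and Trim12a, which lay between 100493337 and 104315558 on chromosome 7, and they may reflect such a segment or the deletion itself.

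Each of the 3 comparisons of groups has 10 splits of its libraries, too few for a share under 0.05, and 1 split, the real one, reached the real count in each. The real split called 129 genes in the callosum against 3 in the highest of the others, 1 gene in neurospheres against 0, and 12645 genes between the wild-type sources against 0. Every other split mixes the real groups on at least 1 side, where a real difference widens the spread. The low counts of those splits therefore do not show what chance alone would give.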

How the results depend on the processing

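Offsets for transcript length and GC content, alone or without 1 library, and the striatal covariate were chosen after seeing the data. The cause of the differences below was not tested, except that a filter or a threshold on size changes how many genes can pass and that a left-out library leaves fewer samples.

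In neurospheres, where 1 gene was called, DESeq2 called 34, limma-voom 2, no filter 5, a single model of 11 libraries 19, and offsets 4, or 4 also without replicate 1 labelled Bmal1-/-. Leaving out 1 library gave 1 to 5. In the callosum, where 129 were called, DESeq2 called 330, no filter 224, a filter at 5 CPM 85, the single model 33 and a threshold of 2-fold 76. Leaving out 1 library gave 27 to 192, the largest without replicate 2 labelled Bmal1-/-, where the lone library left in that group was assumed to vary like the other group. RLE scaling (135), limma-voom (112), offsets (121) and the striatal covariate (100) stayed within 1.5 times. Without TMM scaling 62 callosum genes were higher and 63 lower. For the interaction, where 2 were called, DESeq2 called 37, offsets 10, and offsets without that neurosphere library 15, and leaving out 1 library gave 1 to 10. Without TMM scaling the median of all genes in the interaction moved from 0.04 to 0.13. Genes shared between the sources numbered 1, and 13 with DESeq2 calls or 25 at an unadjusted p under 0.01. Between wild-type sources the count stayed between 9803 and 13707 in every alternative.

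Whether the replicate numbers pair the libraries could not be settled. Libraries of the same number had correlated deviations of 0.279, -0.0119 and 0.309 in neurospheres, where other pairs gave -0.383 to 0.266. In the callosum they were 0.0483 and 0.0101, but the 2 libraries labelled Bmal1-/- deviate as mirror images, so pairing cannot be judged there. With the replicate number as a block, 2 genes were called in neurospheres (Nr1d2 and Per3), 131 in the callosum (94 of the 129 among them), 2 for the interaction and 12557 between wild-type sources. The block turned the callosum log2 fold changes of Arntl to -0.043 and of Per1 to 0.116.

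Gene lists passing camera numbered 8 in neurospheres, 9 in the callosum, 3 for the interaction and 14 between wild-type sources. With an estimated correlation these were 0, 0, 0 and 0, so over these lists that setting did not separate changed from unchanged lists, and with fry 0, 1, 0 and 25. The preset correlation in turn is too low for lists whose genes vary together, so the counts passing with it may be too high. Leaving out 1 library gave 4 to 15, 8 to 13, 2 to 9 and 11 to 14. Direction turned for S phase in neurospheres without wild-type replicate 3 (adjusted p = 0.991, lowest 5.06e-13 over the left-out libraries) and for the respiratory chain in the callosum without replicate 1 labelled Bmal1-/- (adjusted p = 0.316, lowest 7.08e-09).

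For genes of the text that did not pass, some signs turned. In neurospheres, leaving out 1 library gave log2 fold changes of -0.102 to 0.072 for Arntl, -0.24 to 0.224 for Clock, -0.264 to 0.119 for Cry2, -0.056 to 0.663 for Nfil3 and -0.047 to 0.089 for Mmp14. With offsets the values were 0.03 for Arntl, 0.269 for Clock and -0.029 for Mmp14, and also without replicate 1 labelled Bmal1-/- 0.046 for Arntl, 0.293 for Clock and 0.092 for Cry2. In the callosum, leaving out 1 library gave -0.131 to 0.187 for Arntl and -0.142 to 0.123 for Per1. Signs of called genes turned between wild-type sources, where offsets moved Clock from -2.003 to 0.152 (adjusted p = 2.17e-07 and 0.208) and turned 2480 of 12645 calls.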

Other observations

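The tests in this part were set down before the result was seen, except the repeats with offsets and without a library.

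Genes called in the callosum also shifted together in neurospheres beyond the clock. With the clock lists left out, the genes called higher in the callosum (64 tested in neurospheres) had a median log2 fold change of 0.28 there, with 49 above 0, and those called lower (37 tested) had a median of -0.24, with 34 below 0. Camera placed both sets in their own direction (p = 4.83e-07 and 0.000101), and both held with an estimated correlation (p = 0.00749 and 0.0182), with offsets for length and GC content (p = 1.63e-07 and 2.21e-06) and, over 66 and 39 genes, without replicate 1 labelled Bmal1-/- (p = 3.94e-09 and 1.36e-05). An effect of the genotype label common to both sources may account for this, as a hypothesis. A shared strain background of the libraries labelled Bmal1-/- would give the same and was not separated. Sox3 stood at 1.26 ± 0.26 and Fabp7 at 1.19 ± 0.35 in neurospheres, neither passing.

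Other genes among the 17 callosum genes called in every one of 15 settings are named here after their values were seen. The collagen gene Col5a3 rose by 1.77 ± 0.17 on the log2 scale, the collagen prolyl hydroxylase gene P4ha3, which lies within 20 Mb of Arntl, where a donor strain segment or the deletion itself stays open as a cause, by 2.05 ± 0.16, the plasminogen activator gene Plat by 1.29 ± 0.11 and Mmp14 by 1.94 ± 0.13. Also among them were the phosphate transporter gene Slc20a2 (1.42 ± 0.11), the carboxylate transporter gene Slc13a3 (1.53 ± 0.15) and Bcl3, a regulator of NF-kappaB (2.77 ± 0.22), all higher, and Cyp4f15 (-2.10 ± 0.17), lower.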
